A study of Mus musculus with 22 samples.

How the data were processed

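Haematopoietic stem and progenitor populations from the bone marrow of GATA1-GFP transgenic C57BL/6 mice were profiled on Illumina bead arrays, with total RNA amplified to biotin-labelled cRNA. The 22 arrays cover GATA1+LSK (4), GATA1-LSK (4), LMPP (4), CMP (4) and LT-HSC (6), and groups, replicate numbers and slides were taken from the labels. The deposited non-normalised intensity values are linear and include values below 0, so a background had been subtracted on each array. The deposited detection p-value of each probe measures its signal against the negative control beads of that array. The deposited series matrix holds a linear intensity that the authors quantile normalised between arrays. The submitters name BeadStudio without a version, and the background step and annotation are not stated. The labels do not say whether replicates were separate mice.

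The non-normalised intensities were background corrected using the detection p-values and quantile normalised with the neqc function of limma 3.58.1 (offset 16, log2) in R 4.3.3. Of 45281 probes, 34885 named 1 gene, 18 named several and 10378 none, and those of the last kinds were left out. Probes had to be detected (detection p under 0.05) on at least 4 arrays, which 19764 were, 16575 of them with 1 gene. The brightest such probe stood for each of 11118 genes. Detected probes per array ranged from 12264 to 19015. The first principal component held 26.2% of the variance, of which slide accounted for 72.9% and population for 59.9%. These shares overlap because slide and population are partly aligned.

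A group-means model was fitted to all arrays with lmFit and eBayes of limma (17 residual degrees of freedom), and GATA1+LSK was compared with each other population by its two-sided moderated test, Benjamini-Hochberg adjusted over all genes of the comparison, with a threshold of 0.05. Where a gene was detected on no array of the dimmer population, its change is given as at least the ratio of the brighter population's mean to the lowest detected signal on the arrays of the dimmer one. A gene detected on only some of those arrays keeps its measured difference, which is then partly set by background. The 20 gene lists were tested with camera (two-sided, preset inter-gene correlation), adjusted over all 80 tests of lists and comparisons, with camera at an estimated correlation and fry beside it. In every called list the estimated correlation gave a higher adjusted p, which is printed where it ended the call and for some calls that it kept. The lists were erythroid, heme synthesis and iron uptake, megakaryocyte and platelet, GATA1 partners and related transcription factors, mast cell with basophil and eosinophil, lymphoid priming, granulocyte and monocyte progenitor, stem cell, mitosis, DNA replication, ribosome biogenesis, cholesterol synthesis, MHC class II, interferon response, immediate-early and heat shock, and markers of mature neutrophils, macrophages, T and NK cells, B and plasma cells, and stroma and endothelium. Gata1 is in none of them, because the cells were sorted on a GATA1 reporter.

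The lists, comparisons, thresholds, tests, alternative settings and the rule for naming genes were chosen before the data were examined. That rule takes 15 landmark genes, of which 12 were measured, the 10 largest changes in each direction against GATA1-LSK and the 5 largest against each other population, the 5 leading genes of each intersection, and up to 4 called members of each list. The largest changes are those of called genes whose arrays do not overlap, without clone or predicted names. Ear6, Igll1, Mcpt8, Epx and the heat shock genes Hspa1a, Hspa1b and Dnajb1 were named after their values had been seen, and the table of markers of other cell types was written after several of its genes had been seen in the comparisons.

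The alternative settings chosen then were quantile normalisation without background correction, cyclic loess, median scaling, the authors' values as log2 after adding 16, no detection filter and one at detection p under 0.01, the mean of all detected probes, slide as a fixed or random block (statmod 1.5.0), the replicate number as a block, only the populations compared, a variance trend with robust estimation, array weights, leaving out each array in turn, comparisons within a slide and a 2-fold minimum. Leaving out slides 2 or 3 and arrays with raised Ear6 or Igll1 was added after seeing the data. Replicate numbers were read as pairs only where every same-numbered pair of arrays correlated above a minimum fixed beforehand, after centring, which held for CMP (r = 0.194 to 0.591) and LT-HSC (0.247 to 0.648). These correlations are across genes, which are not independent replicates, and 3 of the 4 pairs in each shared a slide. Replicate numbers 5 and 6 occur only in LT-HSC, so the replicate block takes these arrays out of the comparison with LT-HSC. The model fit was tested on simulated log2 values with the mean and spread of each gene, with known changes added to 100 genes at each size. Normalisation, detection filter and choice of probe were not part of this test. The fit recovered 45% to 58% of 2-fold and 90% to 97% of 4-fold changes, and 2.04% to 7.36% of its calls were unchanged genes. The simulated noise was independent between genes and arrays and held no slide effect, so these shares are no error rates of the real calls. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.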

Results

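Gene expression was measured in haematopoietic stem and progenitor populations sorted from the bone marrow of 8-week-old C57BL/6 mice that carried a GATA1-GFP transgene, a fluorescent reporter of the transcription factor GATA1. The 22 arrays fell into 5 populations. GATA1+LSK and GATA1-LSK, the parts of the LSK compartment (enriched for stem and early progenitor cells) with and without the reporter, had 4 arrays each. LMPP (lymphoid-primed multipotent progenitors) and CMP (common myeloid progenitors) had 4 arrays each, and LT-HSC (long-term haematopoietic stem cells) had 6. The title of the series asks for the changes that accompany GATA1 up-regulation, so GATA1+LSK was set against each of the other 4 populations, and every difference below is GATA1+LSK minus the other population on the log2 scale, given ± its standard error (SE) from the fit. Of 45281 probes, 12264 to 19015 were detected per array, and 11118 genes were tested. The number of arrays limits the precision. The labels do not say that replicates came from separate mice, so the p-values measure the spread between these arrays, which may be technical. The arrays lay on 4 slides. Slide 2 was the brightest, with mean signals of 311 to 462 on its 6 arrays, and slide 3 the dimmest, with 123 to 209 on its 6.

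The Gata1 transcript followed the reporter used for sorting. Its mean log2 signal was 7.05 ± 0.66 (SD, n = 4) in GATA1+LSK, 5.64 ± 0.33 (SD, n = 4) in GATA1-LSK, 4.76 ± 0.20 (SD, n = 4) in LMPP, 6.48 ± 0.19 (SD, n = 4) in CMP and 4.996 ± 0.34 (SD, n = 6) in LT-HSC. The difference was 1.40 ± 0.27 from GATA1-LSK (adjusted p = 0.00442), 2.29 ± 0.27 from LMPP (2.73e-06) and 2.05 ± 0.25 from LT-HSC (4.46e-06), and 0.57 ± 0.27, adjusted p = 0.277 from CMP, which did not pass the threshold and was 1.27 within slide 2 and -0.33 within slide 4. With slide as a fixed block the call against GATA1-LSK was lost (values below). The cells were selected on this reporter, so these differences check the labels and are no independent finding.

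**Figure D1:**
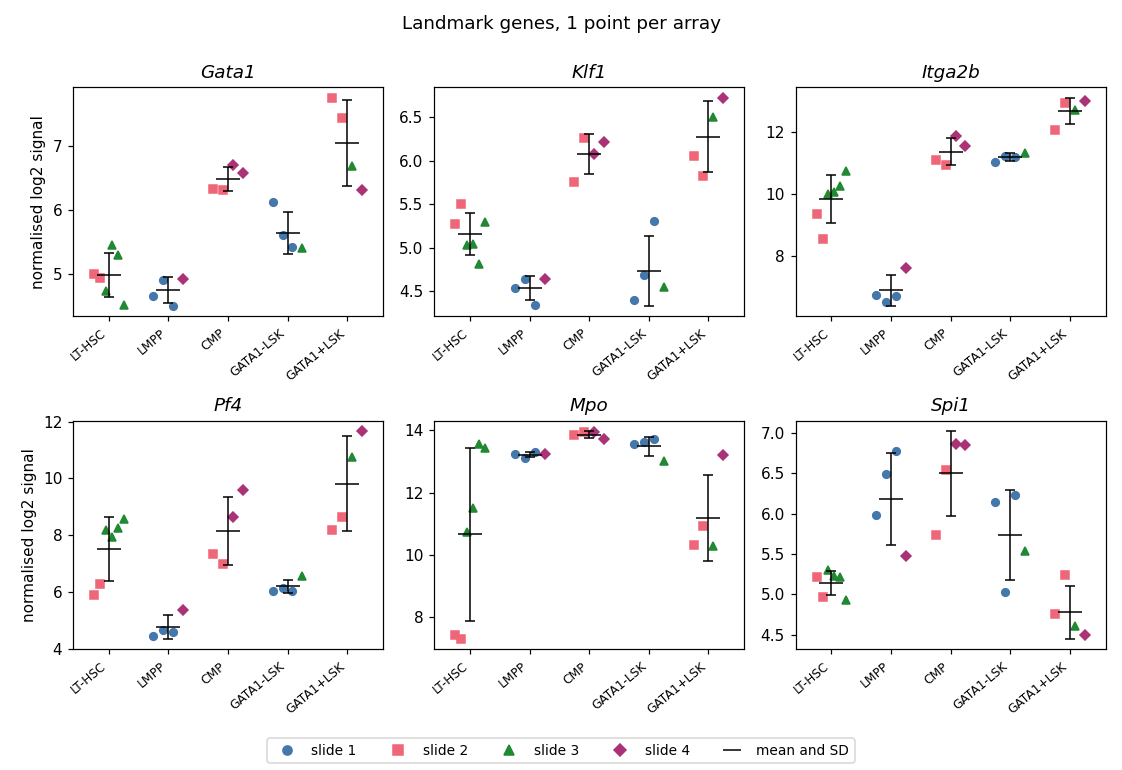
Normalised log2 signal (vertical axis) of 6 landmark genes by population (horizontal axis), 1 point per array, marker shape and colour giving the slide, bars showing the mean and SD. Gata1 averaged 7.05 in GATA1+LSK and 5.64 in GATA1-LSK, and Pf4 averaged 9.81 and 6.19.

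The comparison with GATA1-LSK asks what differs within the LSK compartment between cells with and without the reporter. The megakaryocyte and platelet, erythroid, mitosis, and mast cell, basophil and eosinophil lists were higher in GATA1+LSK. The granulocyte-monocyte and MHC class II lists were lower, which an estimated correlation did not support (adjusted p = 0.0664 and 0.115). Prss34, a serine protease gene known from basophils, was not detected in GATA1-LSK and was at least 57.4-fold higher in GATA1+LSK (adjusted p = 3.98e-12). Prg2, which encodes eosinophil major basic protein, was higher by 5.40 ± 0.81 (adjusted p = 0.000413), and Vwf, which encodes von Willebrand factor, by 2.95 ± 0.31 (adjusted p = 5.41e-06). In all, 311 genes differed, 124 higher and 187 lower in GATA1+LSK, and 254 of them by at least 2-fold. The arrays of the populations did not overlap for 294 of these genes, and over all genes they did not for 9.03%, where chance gives 2.86%. With median scaling in place of quantile normalisation the split was 57 higher and 21 lower.

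Of the 17 measured genes of the megakaryocyte and platelet list, 8 were higher and none was lower (13 adjusted over the list alone, mean 1.41, camera adjusted p = 6.08e-17). Pf4, encoding platelet factor 4, was higher by 3.62 ± 0.69, Gp1bb, a subunit of the platelet receptor for von Willebrand factor, by 3.44 ± 0.43, and Treml1, a platelet receptor gene, by 2.35 ± 0.26. Of 14 erythroid genes, 8 were higher and none lower (11 adjusted over the list alone, mean 1.55, camera adjusted p = 8.72e-16). Car1, a carbonic anhydrase gene, was at least 7.94-fold higher, and Aqp1, a water channel gene, was higher by 2.98 ± 0.28. Klf1, an erythroid transcription factor gene detected on 1 of 4 GATA1-LSK arrays, was higher by 1.55 ± 0.22. Of 8 mast cell, basophil and eosinophil genes, 5 were higher (6 adjusted over the list alone, mean 2.48, camera adjusted p = 2.3e-11). These included Fcer1a, a subunit of the high-affinity IgE receptor (2.37 ± 0.38). Outside these lists, Csrp3, a muscle LIM protein gene, was higher by 4.16 ± 0.49, Cavin2, a caveola component gene, by at least 11.6-fold and Ufsp1, a protease gene, by 3.24 ± 0.24. The mitosis list was higher, with 4 of 14 genes called (11 adjusted over the list alone, mean 1.05, camera adjusted p = 1.9e-12), and so was the DNA replication list, with 2 of 24 (2 adjusted over the list alone, mean 0.34, camera adjusted p = 0.000232). Camera at an estimated correlation gave these lists weaker support (adjusted p = 0.00765 and 0.0401). Tpx2, a spindle assembly factor gene, was higher by 1.56 ± 0.28.

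Among the genes lower in GATA1+LSK, the surface antigen gene Ly6c1 differed by -4.31 ± 0.49 (adjusted p = 1.06e-05) and Bcas1 by -3.45 ± 0.57. They were detected on 1 and 2 of the 4 GATA1+LSK arrays. Sting1, an adaptor in the sensing of cytosolic DNA, differed by -2.85 ± 0.28, Hk3, a hexokinase gene, by -2.74 ± 0.29, Epb41l3 by -2.44 ± 0.32 (with 1 of its 2 other probes going the other way) and Ccl9, a chemokine gene, by -2.31 ± 0.39. Parp3 differed by -2.29 ± 0.51 (adjusted p = 0.0139), a call lost without GATA1+LSK replicates 3 or 4 (adjusted p up to 0.0673). Of 19 granulocyte and monocyte progenitor genes, 3 were lower (6 adjusted over the list alone, mean -1.19, camera adjusted p = 9.55e-07, and adjusted p = 0.0664 with an estimated correlation). They were Hp, encoding haptoglobin (-4.04 ± 0.95, adjusted p = 0.0212), the transcriptional repressor gene Gfi1 (-2.52 ± 0.29) and the proteinase gene Prtn3 (-1.53 ± 0.25). The call of Hp was lost without GATA1+LSK replicate 3 or GATA1-LSK replicates 1 or 2 (adjusted p up to 0.0855). Mpo, encoding myeloperoxidase, differed by -2.30 ± 1.03, adjusted p = 0.297, and Spi1, encoding the transcription factor PU.1, by -0.96 ± 0.30, adjusted p = 0.0984; neither passed the threshold, but Spi1 did without GATA1-LSK replicate 2 (adjusted p = 0.048). Of 10 MHC class II genes, 2 were lower, Cd74 (-2.25 ± 0.39, with 1 of its 2 other probes going the other way) and H2-Eb1 (-2.19 ± 0.42; list 5 adjusted over the list alone, mean -0.89, camera adjusted p = 4.85e-05, and adjusted p = 0.115 with an estimated correlation). Of 16 lymphoid priming genes, 4 were lower (1 higher and 4 lower adjusted over the list alone, mean -0.39, camera adjusted p = 0.0331, and adjusted p = 0.202 with an estimated correlation). Among these were Ltb, encoding lymphotoxin beta (-1.94 ± 0.23), and Satb1, a chromatin organiser gene (-1.75 ± 0.25). That list lost its call without GATA1-LSK replicate 3 (adjusted p = 0.0519), GATA1+LSK replicate 1 (0.0722) or GATA1+LSK replicate 2 (0.0535). The interferon response list had 1 of 13 genes lower, Ifit3 (-1.81 ± 0.44; list 4 adjusted over the list alone, mean -0.44, camera adjusted p = 0.0256, and adjusted p = 0.236 with an estimated correlation). The call of Ifit3 was lost without GATA1+LSK replicate 4 or GATA1-LSK replicates 1, 2 or 4 (adjusted p up to 0.116). The list's call was lost without GATA1+LSK replicates 1, 2 or 4 or GATA1-LSK replicate 4 (adjusted p = 0.0869, 0.119, 0.0786 and 0.144).

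Slide 3, the only slide with both populations, held 1 array of each, and 309 of the 311 genes differed there in the same direction, against 76.4% of all genes. Agreement within a slide is no independent check, here or below, since its arrays took part in the calls. With slide as a fixed block 218 genes were called, 133 of them among the 311. That ended 20 of the 50 calls of genes picked by the naming rule, and leaving out single arrays ended 17 of the 50. The block ended the calls of Gata1 (difference 1.31, adjusted p = 0.0803), the erythroid genes Epor (0.143) and Hba-a1 (0.107) and the heme synthesis gene Urod (0.367). It ended those of the mitosis genes Cdk1 (0.17), Prc1 (0.098) and Cenpa (0.302) and the DNA replication genes Lig1 (0.139) and Rrm1 (0.206). It also ended those of Prg3 (0.0878), Hp (0.329), Cd74 (0.126), H2-Eb1 (0.182), Ifit3 (0.117), Ly6d (0.478), Cd27 (0.139), Tek (0.389), Axl (0.0822), Ptn (0.123) and Rpl3l (0.511), and of the lymphoid priming (0.123) and interferon response (0.141) lists. The count of 311 fell to 179, 179 and 198 without GATA1-LSK replicates 1, 2 and 3, and 200 and 178 without GATA1+LSK replicates 3 and 4.

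**Figure D2:**
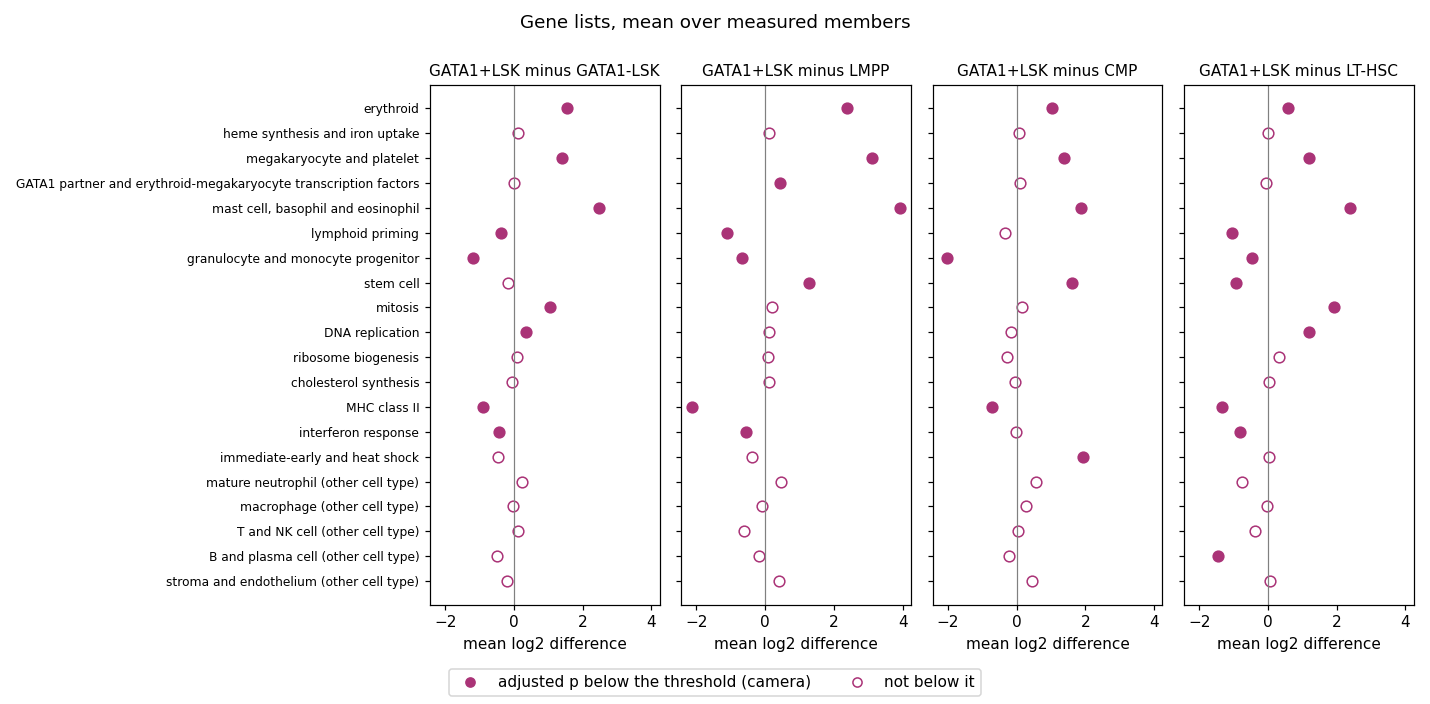
Mean log2 difference (horizontal axis) of the measured members of each fixed gene list (vertical axis) in the 4 comparisons (panels), with filled points where the camera test passed the threshold after adjustment over all 80 tests. The megakaryocyte and platelet list was higher in every panel, from 1.20 against LT-HSC to 3.11 against LMPP.

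LMPP are the lymphoid-biased progenitors of the LSK compartment. Against them megakaryocyte, erythroid and stem cell transcripts were higher in GATA1+LSK, and lymphoid and MHC class II transcripts were lower. Treml1 was at least 67.8-fold higher in GATA1+LSK (adjusted p = 3.54e-13), and Itga2b, encoding the CD41 integrin subunit, was higher by 5.78 ± 0.36 (adjusted p = 1.31e-10). Dntt, encoding the terminal transferase of lymphoid progenitors, was not detected in GATA1+LSK and was at least 14.6-fold higher in LMPP (adjusted p = 1.24e-09). In all, 955 genes differed, 414 higher and 541 lower in GATA1+LSK, and 750 of them by at least 2-fold. The arrays of the populations did not overlap for 855 of these genes, and over all genes they did not for 13.8%, where chance gives 2.86%.

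Of 17 megakaryocyte and platelet genes, 12 were higher (13 adjusted over the list alone, mean 3.11, camera adjusted p = 1.33e-27). They included Vwf (5.54 ± 0.31) and Pf4 (5.05 ± 0.69, detected on 1 of 4 LMPP arrays). Of 14 erythroid genes, 12 were higher (12 adjusted over the list alone, mean 2.38, camera adjusted p = 1.2e-18). Aqp1 differed by 6.14 ± 0.28 and Epor, the erythropoietin receptor gene, by 1.45 ± 0.23, and Klf1 was at least 2.61-fold higher. The mast cell, basophil and eosinophil list had 6 of 8 genes higher (8 adjusted over the list alone, mean 3.94, camera adjusted p = 1.78e-14). Prg2 differed by 7.53 ± 0.81 and the protease gene Cpa3 by 3.81 ± 0.40, and Prss34 was at least 59.8-fold higher. Csrp3 was at least 60.2-fold higher. Of 19 stem cell genes, 11 were higher and 2 lower (13 higher and 2 lower adjusted over the list alone, mean 1.28, camera adjusted p = 6.02e-10). The higher ones included the transglutaminase gene Tgm2 (4.46 ± 0.49) and the adhesion molecule gene Esam (3.88 ± 0.23). The list of GATA1 partners and related transcription factors had 3 of 14 genes higher, Gata2 (2.87 ± 0.34), Gfi1b (2.38 ± 0.35) and Tal1 (1.23 ± 0.22; list 4 higher and 3 lower adjusted over the list alone, mean 0.42, camera adjusted p = 0.0331, and adjusted p = 0.408 with an estimated correlation). Its call was lost without LMPP replicate 3 (adjusted p = 0.0884), GATA1+LSK replicate 1 (0.089) or GATA1+LSK replicate 2 (0.0969). Bgn, the biglycan gene, was higher by 4.005 ± 0.22, while the stroma and endothelium list that holds it was not called (adjusted p = 0.492).

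Of 10 MHC class II genes, 8 were lower in GATA1+LSK (9 adjusted over the list alone, mean -2.14, camera adjusted p = 6.06e-12), H2-Eb1 by -4.61 ± 0.42 and Cd74 by -4.14 ± 0.39. Of 16 lymphoid priming genes, 6 were lower (7 adjusted over the list alone, mean -1.13, camera adjusted p = 1.17e-06). Satb1 differed by -4.14 ± 0.25 and the receptor gene Notch1 by -2.54 ± 0.28. Of 19 granulocyte and monocyte progenitor genes, 5 were lower (1 higher and 8 lower adjusted over the list alone, mean -0.67, camera adjusted p = 0.00131, and adjusted p = 0.236 with an estimated correlation), Gfi1 by -3.25 ± 0.29, and Irf8, a regulator of monocyte and dendritic cell development, was at least 3.09-fold higher in LMPP. The interferon response list had 3 of 13 genes lower (1 higher and 4 lower adjusted over the list alone, mean -0.55, camera adjusted p = 0.0203, and adjusted p = 0.225 with an estimated correlation), Ifit3 by -2.40 ± 0.44, and lost its call without GATA1+LSK replicates 1, 2 or 4 (adjusted p = 0.0627, 0.0731 and 0.0514). Cox6a2, a cytochrome oxidase subunit gene, was not detected in GATA1+LSK and was at least 80.2-fold higher in LMPP, and Cass4 (-4.59 ± 0.68), the interleukin 10 receptor gene Il10ra (-4.54 ± 0.25) and Emp1 (-4.50 ± 0.49) were also lower in GATA1+LSK. On slide 4, the only slide with both populations (1 array of each), 943 of the 955 genes differed in the same direction (all genes 75.7%), but the transcription factor list had a mean of -0.02 and the granulocyte and monocyte list one of 0.10. With slide as a fixed block 870 genes were called, 640 of them among the 955, and neither of those lists was (adjusted p = 0.151 and 0.161). Of 57 calls of genes picked by the naming rule 9 ended.

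CMP are myeloid progenitors outside the LSK compartment. Against them stem cell, megakaryocyte and immediate-early transcripts were higher in GATA1+LSK, and granulocyte and monocyte transcripts were lower. Egr1, an immediate-early transcription factor gene, was higher by 4.80 ± 0.30 (adjusted p = 6.72e-10). F13a1, a coagulation factor XIII subunit gene, was not detected in GATA1+LSK and was at least 28-fold higher in CMP (adjusted p = 6.86e-13). Klf1 (0.20 ± 0.22, adjusted p = 0.745) did not pass the threshold. In all, 718 genes differed, 384 higher and 334 lower in GATA1+LSK, 558 of them by at least 2-fold, and 1118 were called with the replicate number as a block. The arrays of the populations did not overlap for 651 of these genes, and over all genes they did not for 10.8%, where chance gives 2.86%. With median scaling the split was 106 higher and 239 lower, about a median of all genes of -0.22.

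Of 19 granulocyte and monocyte progenitor genes, 9 were lower in GATA1+LSK (12 adjusted over the list alone, mean -2.03, camera adjusted p = 1.63e-13). Among them were Hp (-6.14 ± 0.95), the neutrophil elastase gene Elane (-4.60 ± 1.01), Ly86 (-3.38 ± 0.37) and Spi1 (-1.72 ± 0.30), and Irf8 was at least 7.39-fold higher in CMP. Mpo differed by -2.68 ± 1.03 (adjusted p = 0.149, 0.0143 with the replicate block and 0.0289 with slide as a fixed block). Ly6c1 differed by -5.43 ± 0.49 and Ccl9 by -5.27 ± 0.39, and the calcium channel gene Cacna1d was at least 24-fold higher in CMP, although its other probe did not go the same way. The MHC class II list had 2 of 10 genes lower (4 adjusted over the list alone, mean -0.71, camera adjusted p = 0.00148, and adjusted p = 0.227 with an estimated correlation). Of 19 stem cell genes, 11 were higher and none lower (15 adjusted over the list alone, mean 1.62, camera adjusted p = 4.97e-19). These included Tgm2 (3.96 ± 0.49), the cyclin-dependent kinase inhibitor gene Cdkn1c (3.56 ± 0.24), Esam (3.52 ± 0.23) and Ndn (2.86 ± 0.37). The megakaryocyte and platelet list had 11 of 17 genes higher (12 adjusted over the list alone, mean 1.39, camera adjusted p = 3.97e-14). Mmrn1 differed by 2.95 ± 0.50, Gp9 by 2.59 ± 0.24 and Vwf by 2.45 ± 0.31. Pf4 differed by 1.66 ± 0.69 (adjusted p = 0.192, 0.0152 with the replicate block and 4.57e-05 with slide as a fixed block). The erythroid list had 5 of 14 genes higher (8 adjusted over the list alone, mean 1.02, camera adjusted p = 5.13e-06), with the carbonic anhydrase gene Car2 at 1.97 ± 0.36. The mast cell, basophil and eosinophil list had 3 of 8 higher (5 higher and 1 lower adjusted over the list alone, mean 1.87, camera adjusted p = 0.00025, and adjusted p = 0.0635 with an estimated correlation). Prg2 differed by 7.29 ± 0.81 and Prss34 by 5.21 ± 0.28. Bgn was higher by 3.87 ± 0.22.

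Of 15 immediate-early and heat shock genes, 9 were higher in GATA1+LSK than in CMP (12 adjusted over the list alone, mean 1.94, camera adjusted p = 3.01e-13, and adjusted p = 0.037 with an estimated correlation). The transcription factor gene Jun differed by 2.93 ± 0.64 and the mRNA decay factor gene Zfp36 by 2.60 ± 0.44. Against GATA1-LSK, LMPP and LT-HSC the list was not called (adjusted p = 0.244, 0.492 and 0.944), and the comparisons were not tested against each other. Its mean difference from CMP was 2.68 within slide 2 (2 arrays of each population) and 1.23 within slide 4 (1 array of GATA1+LSK and 2 of CMP). Over all 718 genes the direction held for 717 within slide 2 and 710 within slide 4 (all genes 75.6% and 79.6%). With slide as a fixed block 1445 genes were called, 717 of them among the 718, and 0 of 50 calls of genes picked by the naming rule ended.

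LT-HSC are the long-term stem cells. Against them mitosis, DNA replication and megakaryocyte transcripts were higher in GATA1+LSK, and stem cell, lymphoid and interferon response transcripts were lower. Prss34 was not detected in LT-HSC and was at least 53.7-fold higher in GATA1+LSK (adjusted p = 4.95e-13), and Itga2b was higher by 2.84 ± 0.33 (adjusted p = 2.84e-06). Vwf (-0.42 ± 0.28, adjusted p = 0.458), Gata2 (0.37 ± 0.31, adjusted p = 0.574) and Mpo (0.53 ± 0.94, adjusted p = 0.843) did not pass the threshold. The difference of Mpo was 3.27 within slide 2 and -2.02 within slide 3, and that of Vwf was -1.38 within slide 2 (adjusted p = 0.00196) and 0.10 within slide 3. In all, 1172 genes differed, 468 higher and 704 lower in GATA1+LSK, and 796 of them by at least 2-fold. The arrays of the populations did not overlap for 744 of these genes, and over all genes they did not for 7.87%, where chance gives 0.952%.

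Of 14 mitosis genes, 13 were higher (14 adjusted over the list alone, mean 1.91, camera adjusted p = 8.64e-19). They included the kinase genes Aurkb (2.51 ± 0.32) and Cdk1 (2.32 ± 0.23) and the topoisomerase gene Top2a (2.37 ± 0.39). Of 24 DNA replication genes, 16 were higher (20 adjusted over the list alone, mean 1.19, camera adjusted p = 8.55e-19). The thymidine kinase gene Tk1 differed by 2.27 ± 0.24 and the helicase subunit gene Mcm2 by 1.86 ± 0.20. The megakaryocyte and platelet list had 10 of 17 genes higher (12 adjusted over the list alone, mean 1.20, camera adjusted p = 2.5e-09). Gp1bb differed by 2.74 ± 0.39 and Gp5 by 2.36 ± 0.27. The erythroid list had 6 of 14 genes higher and 1 lower (6 higher and 1 lower adjusted over the list alone, mean 0.60, camera adjusted p = 0.00484, and adjusted p = 0.115 with an estimated correlation). Klf1 differed by 1.12 ± 0.20 and, as the lower gene, the sphingosine kinase gene Sphk1 by -2.13 ± 0.33. Epor was higher by 0.71 ± 0.21 (adjusted p = 0.0291), a call lost with the replicate block (adjusted p = 0.0567) and without GATA1+LSK replicates 1, 2 or 3 or LT-HSC replicates 1, 2 or 6 (adjusted p up to 0.0982). The mast cell, basophil and eosinophil list had 3 of 8 higher (5 adjusted over the list alone, mean 2.40, camera adjusted p = 3.98e-08), with Fcer1a at 3.94 ± 0.35. Csrp3 (4.38 ± 0.44), the transporter gene Mfsd2b (3.18 ± 0.25) and the actin-severing protein gene Scin (3.10 ± 0.36) were also higher.

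Of 19 stem cell genes, 10 were lower in GATA1+LSK (1 higher and 11 lower adjusted over the list alone, mean -0.93, camera adjusted p = 3.24e-07). The lower genes included the sulfotransferase gene Sult1a1 (-3.92 ± 0.39), the receptor gene Robo4 (-2.24 ± 0.28) and Cdkn1c (-1.997 ± 0.22). Of 16 lymphoid priming genes, 7 were lower (8 adjusted over the list alone, mean -1.05, camera adjusted p = 2.52e-06). Ltb differed by -2.57 ± 0.21 and the interleukin 7 receptor gene Il7r by -1.98 ± 0.42. Ly6d, a marker of early lymphoid cells, was not detected in GATA1+LSK and was at least 14.6-fold higher in LT-HSC. Mzb1, a gene of B cells, differed by -4.73 ± 0.47. The B and plasma cell list had 2 of 4 genes lower (3 adjusted over the list alone, mean -1.46, camera adjusted p = 0.000396, and adjusted p = 0.0612 with an estimated correlation), Pou2af1, a B cell coactivator gene, by -2.71 ± 0.35. B cell progenitor transcripts differed between the LT-HSC arrays: Igll1, a surrogate light chain gene, stood at 8.6 and 9.18 in replicates 3 and 4 and at 4.29 to 5.94 in the other 4. Without replicates 3 and 4, an alternative chosen after seeing the data, 978 genes differed from LT-HSC. The MHC class II list had 5 of 10 genes lower (5 adjusted over the list alone, mean -1.35, camera adjusted p = 2.76e-05, and adjusted p = 0.107 with an estimated correlation), Cd74 by -4.19 ± 0.36. The interferon response list had 6 of 13 lower (7 adjusted over the list alone, mean -0.80, camera adjusted p = 8.36e-05, and adjusted p = 0.0401 with an estimated correlation), Ifit3 by -3.21 ± 0.40.

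The granulocyte and monocyte list had 3 of 19 genes lower than in LT-HSC (3 adjusted over the list alone, mean -0.47, camera adjusted p = 0.0263, and adjusted p = 0.442 with an estimated correlation), Gfi1 by -3.02 ± 0.26. Its direction differed between slides, with a mean of 0.47 within slide 2 (2 arrays of each population) and -1.32 within slide 3 (1 array of GATA1+LSK and 4 of LT-HSC). Its call was lost with slide as a fixed block (adjusted p = 0.141), with the replicate block (mean 0.12, adjusted p = 0.635) and without GATA1+LSK replicates 1 or 3 or LT-HSC replicates 5 or 6 (adjusted p = 0.0768, 0.0589, 0.11 and 0.14). The replicate block also takes LT-HSC replicates 5 and 6 out of the comparison, so it is no separate check from leaving them out. Over all 1172 genes the direction held for 1162 within slide 2 and 1167 within slide 3 (all genes 72.2% and 77.2%). With slide as a fixed block 1707 genes were called, 1069 of them among the 1172, and 1 of 59 calls of genes picked by the naming rule ended.

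Genes that differed from all 4 other populations in 1 direction numbered 27 higher and 32 lower in GATA1+LSK. The higher genes were led by Prss34, whose smallest difference was 5.21, followed by Gp1bb (2.41), Ufsp1 (2.13), Treml1 (1.97) and the growth factor gene Ptn (1.96). The lower genes were led by Gfi1 (smallest difference -2.52, against GATA1-LSK), Rpl3l (-2.07), Bcas1 (-2.003, against CMP), Sting1 (-1.94, against LT-HSC) and the glutathione transferase gene Mgst1 (-1.86). The calls against GATA1-LSK of Ptn (adjusted p = 0.123) and Rpl3l (0.511) were lost with slide as a fixed block, and on leaving out arrays so were those of Rpl3l against GATA1-LSK (adjusted p up to 0.131, without GATA1+LSK replicates 3 or 4 or GATA1-LSK replicates 1, 2 or 3), of Rpl3l against CMP (up to 0.0639, without CMP replicate 3 or GATA1+LSK replicates 3 or 4) and of Bcas1 against CMP (up to 0.0952, without any of the 8 arrays). The 4 comparisons share the GATA1+LSK arrays. In 100 simulations all arrays were replaced by independent noise with the spread of each gene and no difference between populations. The highest count was then 0 in either direction, which the adjustment makes near certain when nothing differs, so it tests little. At an unadjusted p under 0.05 the highest was 22 higher and 24 lower, against 88 and 134 observed. The noise held no correlation between genes and no slide effect, so it cannot exclude these as contributors. Independent lists of the observed sizes would share 0.00671 and 0.0173 genes. The GATA1+LSK arrays were also divided evenly, with some used against GATA1-LSK and LMPP and the rest against CMP and LT-HSC. The 6 divisions of this kind gave 13 to 20 higher and 13 to 18 lower genes. The comparisons with GATA1-LSK and LMPP still shared their arrays, as did those with CMP and LT-HSC, so sharing was only partly removed.

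Transcripts of eosinophil granules varied between arrays of GATA1+LSK and LT-HSC. Ear6, an eosinophil-associated ribonuclease gene, stood at 9.16 and 11.8 in GATA1+LSK replicates 3 and 4 and at 11.2 and 9.69 in LT-HSC replicates 5 and 6, and did not exceed 5.27 in the other 18. Without those 4 arrays, an alternative chosen after seeing the data, 112 genes differed from GATA1-LSK, 675 from LMPP, 661 from CMP and 778 from LT-HSC. The GATA1+LSK arrays left were replicates 1 and 2, both on slide 2, which holds no array of GATA1-LSK or LMPP. Raised Ear6 and slide therefore cannot be told apart as reasons for these changes. The lymphoid priming list against GATA1-LSK (adjusted p = 0.0545) and the erythroid (0.0889) and granulocyte and monocyte (0.346) lists against LT-HSC were then not called.

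**Figure D3:**
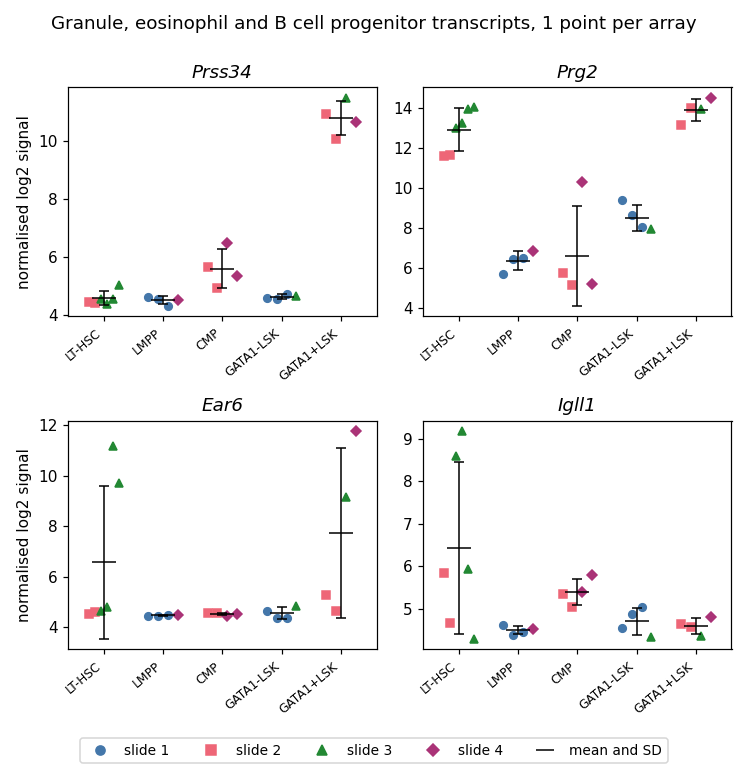
Normalised log2 signal (vertical axis) of Prss34, Prg2, Ear6 and Igll1 by population (horizontal axis), 1 point per array, marker shape and colour giving the slide, bars showing the mean and SD. Prss34 averaged 10.8 in GATA1+LSK and at most 5.59 in the other populations, while Ear6 reached 11.8 and Igll1 9.18 on a few arrays.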

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

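The tests of Prg2 and Prss34, of the immediate-early list and of the lymphoid priming list below were chosen, with their thresholds, after these results had been seen, whereas the counts of other splits were planned.

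Few splits of the arrays called as many genes as the real one, but this does not exclude chance. A split that mixes the populations widens the spread within its groups, which keeps its count low (median of the other splits 0 in each comparison). The arrays may also be technical repeats. Against GATA1-LSK and LMPP, 1 and 1 of 35 splits of the 8 arrays, the real one, called as many genes (311 and 955), and the highest other split called 1 in each. Against CMP 1 of 35 splits called the real 718, and the highest other (647) was the split that sets the arrays of slide 2 against the rest, which points to slide as a structure of the samples. With slide as a fixed block that comparison called 1445 genes. Against LT-HSC 3 of 100 drawn splits of 210 called 1172 or more, and the highest, 3325, again set slide 2 against the rest. With slide as a fixed block the real split called 1707, a count from another model that cannot be set against 3325. Among splits that part all 4 replicate pairs, as the real ones do, the highest other called 5 genes against CMP (8 splits) and 5 against LT-HSC (6 splits). For the genes higher and lower than all 4 populations, 1 of 100 relabelings gave as many (27 and 32), the highest other 0. For the 36 list tests called, 1 of 100 did, but the highest other called 35. A relabeling that called 35 shows that camera at its preset correlation can call nearly as many lists without the real labels. The count of list tests therefore does not exclude chance. Nor do those relabelings exclude slide, since they keep neither slide nor replicate number. Of list tests, 31 were called with slide as a fixed block, with the replicate block 33 and with an estimated correlation 23.

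Prg2 stood above log2 8 with Ear6, Prg3 and Epx, other eosinophil granule genes, all below log2 6 on 5 of the 10 GATA1+LSK and LT-HSC arrays, and Prss34 averaged 10.8 in GATA1+LSK. The log2 difference of Prg2 and Ear6 ranged over at least 6.60 units and that of Prg2 and Prg3 over at least 4.53 (Prg2 and Epx 2.43). The first 2 are lower bounds because the partner was near background on some arrays. Epx was near background too (lowest 4.71 in GATA1+LSK and 4.44 in LT-HSC), so its range of 2.43 does not show that the true range is small. Cells that hold these transcripts in a fixed proportion would give a small range. This argues against such eosinophils as the whole source, but not against eosinophil-lineage cells in which the proportion differs. Basophils or mast cells as a source of Prss34 stay open, since the difference of Prss34 and Mcpt8, another basophil protease gene, ranged over 2.41 units on 4 arrays, between the limits set for either answer. Mcpt8 was higher than in GATA1-LSK by 1.85 ± 0.41 (adjusted p = 0.0128) and Fcer1a by 2.37 ± 0.38 (adjusted p = 0.000801). Cpa3 (-0.07 ± 0.40, adjusted p = 0.965), Hdc (-0.47 ± 1.17, adjusted p = 0.907) and Ccl3 (-0.83 ± 0.39, adjusted p = 0.326) did not pass the threshold against GATA1-LSK. Against CMP, where Prss34 was 5.21 higher, Mcpt8 differed by -0.01 ± 0.41 (adjusted p = 0.997) and Cpa3 by -1.25 ± 0.40 (adjusted p = 0.0695). Hdc differed from CMP by -1.89 ± 1.17 (adjusted p = 0.461), Ccl3 by -1.27 ± 0.39 (adjusted p = 0.0578) and Fcer1a by 1.16 ± 0.38 (adjusted p = 0.0744). None of these differences from CMP passed the threshold, so they decide nothing about such cells. CMP may also express these genes themselves (Cpa3 stood at 9.95 there and at 8.77 in GATA1-LSK). Ccl3 was highest in LMPP (9.20), where Prss34 was not detected, so it does not follow Prss34. Of 9 eosinophil and 10 basophil and mast cell markers, 3 and 5 were measured, 4 and 8 also stand in a fixed list, and the lineage-negative LSK gate should remove mature cells of these types, and expression by the GATA1+LSK cells themselves, a biological difference of the sorted populations, stays open and untested.

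The immediate-early and heat shock list was lower in CMP than in GATA1+LSK. Slide as the cause is argued against by a mean difference of 2.68 within slide 2 and 1.23 within slide 4. Handling of the CMP samples before lysis stays open: the heat shock members differed by 1.51 (Hspa1a), 0.62 (Dnajb1) and 0.36 (Hspa1b), neither all large nor all near 0, and the labels give no record of handling by population. A difference between the cell populations stays open and was not tested.

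The lymphoid priming list was higher in LT-HSC than in GATA1+LSK, and Igll1 stood at 8.6 and 9.18 in LT-HSC replicates 3 and 4. B cell progenitors in those 2 arrays alone are argued against as the whole cause, because without them the list was still lower in GATA1+LSK (mean -0.78, adjusted p = 2.88e-05, against a mean of -1.05 over all arrays), as it was without all 4 LT-HSC arrays with Igll1 and Vpreb3 detected (mean -0.77, adjusted p = 0.000103). Other B cell transcripts remained in the arrays kept. Pou2af1 was detected on all 6 LT-HSC arrays. Within slide 2 it differed by -3.40, and the B and plasma cell list averaged -1.40. Leaving arrays out therefore cannot decide about B cell progenitors spread over all LT-HSC arrays, which stay open. Slide is argued against by an adjusted p of 3.5e-05 with slide as a fixed block. Of 8 B cell progenitor markers 6 were measured, all 8 stand in a fixed list, and an LT-HSC sort should remove such cells. A difference between the cell populations stays open as a hypothesis.

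Single arrays far from the others of their population, by the gap to the nearest in relation to the whole range, were found in 18 of 366 tests (4.92%), where chance gives about 5%. In GATA1+LSK replicate 4 the log2 signal of Gfi1 was 7.47, against 5.9 to 6.07 in the others, that of Cd74 4.38, against 4.79 to 4.84 in the others, of Treml1 11.5, against 10.8 to 10.9 in the others, of Ifit3 4.59, against 6.36 to 6.56 in the others, of H2-Aa 5.56, against 4.48 to 4.64 in the others and of Elane 7.56, against 5.56 to 5.67 in the others. In GATA1+LSK replicate 3 that of Bcl11a was 11, against 10.3 to 10.4 in the others. In GATA1-LSK replicate 4 that of Csrp3 was 8.01, against 6.06 to 6.36 in the others, of Car1 4.41, against 4.57 to 4.59 in the others and of Fcer1a 4.54, against 6.52 to 6.91 in the others. In LMPP that of Cass4 was 9.74, against 10.2 to 10.3 in the others (replicate 4) and that of Gp1bb 4.56, against 4.29 to 4.32 in the others (replicate 3). In CMP replicate 3 Prg2 stood at 10.3, against 5.17 to 5.78 in the others, and Cdkn1c at 7.38, against 6.41 to 6.57 in the others. Irf8 stood at 8.83, against 7.48 to 7.57 in the others in CMP replicate 4, and Cd74 at 5.58, against 6.42 to 6.59 in the others in CMP replicate 1. Prss34 stood at 5.03, against 4.39 to 4.55 in the others in LT-HSC replicate 6. The share of probes detected in GATA1-LSK replicate 3 was 36.8%, against 33.4% to 33.9%.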

How the results depend on the processing

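Leaving out slide 2 or 3 and arrays with raised Ear6 or Igll1 was chosen after seeing the data, and the level of log2 8 for the latter was set after a first definition by detection had been run. Apart from leaving out single arrays, 102 of 141 alternative counts stayed within 1.5 times the one reported. Of alternative tests of called lists, 716 of 756 kept direction and call, and of called named genes 3924 of 4429. Without single arrays, 95 of 100 counts, 293 of 310 list tests and 1639 of 1846 gene tests stayed so, with ranges of 178 to 372 genes against GATA1-LSK, 746 to 980 against LMPP, 516 to 716 against CMP, 939 to 1177 against LT-HSC, 19 to 33 higher and 25 to 40 lower than all 4, and 31 to 37 list tests. The GATA1-LSK count was 178 without GATA1+LSK replicate 4 and 372 without GATA1+LSK replicate 1.

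In the order GATA1-LSK, LMPP, CMP and LT-HSC, median scaling gave 78, 447, 345 and 497 genes, with 9 higher and 7 lower than all 4. It moved the median of all genes to -0.11 against LMPP and -0.22 against CMP, and the share of higher calls from 39.9% to 73.1% against GATA1-LSK and from 53.5% to 30.7% against CMP. Array weights gave 1136, 2140, 2653 and 2892, with 74 and 117, and ended the call of the erythroid list against LT-HSC (adjusted p = 0.329). Fitting only the populations compared gave 165 (GATA1-LSK), 476 (CMP) and 658 (LT-HSC), with 18 lower than all 4. The replicate block gave 581 (GATA1-LSK) and 1118 (CMP), with 42 and 50. Same-numbered arrays of GATA1+LSK did not pair with those of GATA1-LSK (r = -0.174 to 0.282 across genes, 2 of 4 best with their own number) or LMPP (0.0245 to 0.426, 1 of 4). There the block changed the calls of Csf3r, Urod and the lymphoid priming and transcription factor lists. Against CMP and LT-HSC it changed, besides the calls given above, that of Nop58 against LT-HSC (adjusted p = 0.148), and no other of a named gene or list. Slide as a fixed and as a random block gave 1445 and 1310 against CMP, and slide 2 alone 1501 against CMP and 1946 against LT-HSC. Without slide 2 there were 1728 (GATA1-LSK) and 2198 (LMPP), with 72 and 87, from GATA1+LSK replicates 3 and 4, the arrays with raised Ear6. Without arrays with Ear6 above log2 8 there were 112 (GATA1-LSK) and 778 (LT-HSC), with 17 lower than all 4, from GATA1+LSK replicates 1 and 2 on slide 2. Without those with Ear6 detected, 28, 319, 254 and 305, with 8 and 3, from a lone GATA1+LSK array assumed to vary like the others. Without those with Igll1 and Vpreb3 detected, 695 genes differed from LT-HSC. With an estimated correlation 23 of 80 list tests were called, against 36 with the preset one, and fry called 41. The lymphoid priming list against GATA1-LSK lost its call with cyclic loess (adjusted p = 0.0689) and median scaling (0.0655), and the granulocyte and monocyte list against LT-HSC with cyclic loess (0.0828). A result counted as reversed if its direction changed and it was called over all arrays or in the alternative. This held for the granulocyte and monocyte list against LT-HSC without slide 3 (0.74, adjusted p = 0.128). The mean of that list was also above 0 within slide 2 (0.47), with the replicate block (0.12) and without arrays with Ear6 detected (0.02). It also held for Slamf1 against LT-HSC within slide 2 (-0.95, adjusted p = 0.00584), which over all arrays differed by 0.40 and was not called. Uncalled changes of direction within a slide, such as those of Mpo and Gata1 given above, are not counted. Leaving arrays out shrinks the groups, and for the other changes the cause was not tested. Signal over background limits genes near the detection limit, such as Klf1 in LMPP, where only a lower bound is given.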

Other observations

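The tests of the fixed lists and landmark genes in this part were planned, and none was chosen after its result had been seen.

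The mitosis and DNA replication lists, higher in GATA1+LSK than in LT-HSC (13 of 14 and 16 of 24 genes called) and, with few genes called, than in GATA1-LSK (4 of 14 and 2 of 24), did not pass the threshold against LMPP or CMP. The lists kept their calls against GATA1-LSK with slide as a fixed block (adjusted p = 6.57e-12 and 0.00021), but of those genes only Tpx2 did. The mitosis list averaged a log2 signal of 9.82 ± 0.16 (SD, n = 4) in GATA1+LSK, 8.78 ± 0.21 in GATA1-LSK, 9.63 ± 0.19 in LMPP, 9.66 ± 0.17 in CMP and 7.91 ± 0.52 (n = 6) in LT-HSC, with an adjusted p of 0.253 against LMPP and 0.347 against CMP. The DNA replication list had 0.234 and 0.454. Whether these differences themselves differ between comparisons was not tested. The stem cell list averaged 8.52 ± 0.18 in GATA1+LSK and 8.68 ± 0.07 in GATA1-LSK (adjusted p = 0.34), 9.45 ± 0.30 in LT-HSC, 7.24 ± 0.13 in LMPP and 6.89 ± 0.10 in CMP. Slamf1, which encodes the stem cell marker CD150, differed from GATA1-LSK by 1.32 ± 0.42, adjusted p = 0.105 and from LT-HSC by 0.40 ± 0.38, adjusted p = 0.641, neither past the threshold. It was at least 1.98-fold higher than in LMPP (adjusted p = 0.0366) and 1.98-fold than in CMP (0.0487), calls each lost without any of 7 of the 8 arrays (adjusted p up to 0.141 and 0.163). Flt3, the receptor gene that marks LMPP, was near the detection limit, detected on 2 of 4 GATA1+LSK and 3 of 4 LMPP arrays, and differed from LMPP by -0.32 ± 0.17, adjusted p = 0.311. Csf3r, the G-CSF receptor gene, differed by -0.83 ± 0.30, adjusted p = 0.158 from GATA1-LSK. Gata2 differed by 0.64 ± 0.34, adjusted p = 0.407 from GATA1-LSK and 0.81 ± 0.34, adjusted p = 0.191 from CMP, where it was called with slide as a fixed block (adjusted p = 0.011).

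Several fixed lists passed the threshold in none of the 4 comparisons. Their camera adjusted p ranged over 0.34 to 0.869 for heme synthesis and iron uptake, 0.0676 to 0.579 for ribosome biogenesis, 0.284 to 0.944 for cholesterol synthesis, 0.442 to 0.612 for mature neutrophil, 0.314 to 0.895 for macrophage, 0.167 to 0.94 for T and NK cell and 0.298 to 0.795 for stroma and endothelium genes. Single members were called, among them Axl, a receptor gene of macrophages, which differed by -1.48 ± 0.20 from LT-HSC, -0.97 ± 0.22 from GATA1-LSK and, the other way, 0.92 ± 0.22 from CMP, and Klrd1, an NK cell receptor gene, by -1.72 ± 0.35 from LT-HSC. The call of Axl against GATA1-LSK was lost with slide as a fixed block (adjusted p = 0.0822) and without GATA1+LSK replicate 3 or GATA1-LSK replicate 1 (adjusted p up to 0.0565). The mature neutrophil list varied between the LT-HSC arrays, from a mean log2 signal of 4.86 to 7.76 (SD 1.215). Its mean difference from LT-HSC was 0.95 within slide 2 and -1.72 within slide 3, so the uncalled result averages arrays that differ.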
